A study of Homo sapiens with 30 samples.

How the data were processed

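Ribonucleic acid was prepared as libraries with a directional kit from 1 ug of total RNA and sequenced as 100 bp paired-end reads, per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to hg38/GRCh38 and quantified with RSEM 1.3.3, per the submitters' processing notes. The authors deposited expected counts per Ensembl gene. That unit was inferred from the values, which were not negative and of which 23.339 to 25.423% were not whole numbers in a library. The annotation release and whether counting used strand are not given in the sources used here.

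The table held 60675 genes and 269 library columns. The 30 columns that the sample labels describe were used, and the remaining 239 columns were not used here. Sample labels give 0.1% DMSO for the vehicle and the series design 2%, a conflict that could not be settled. Hot-water extracts, wortmannin and doses based on toxicity, which the design also names, were not analysed here. All labels carry the same batch name, but the sample codes of vehicle and extract libraries start with different codes, so any handling difference tied to them coincides with treatment. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

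Counts were rounded to whole numbers, which changed a library total by at most 0.0002%. Symbols were matched for 56558 genes, and positions (GRCh38) came from GENCODE release 29, with 57055 genes matched. Genes were kept by filterByExpr with a minimum count of 10, which left 18227. Libraries were scaled by the trimmed mean of M values, with factors from 0.9 to 1.03. One model with a mean for each of the 13 groups was fitted by quasi-likelihood in edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with 17 residual degrees of freedom and a common biological coefficient of variation of 0.0553. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Values in CPM are means ± SD over libraries. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures with matplotlib 3.10.9.

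Comparisons, gene lists and the rule for named genes were fixed before the data were examined. The 28 lists, written from general knowledge, had 585 entries, of which 574 matched a gene. A total of 26 lists had at least 5 tested members, and the leukocyte and endothelial lists, with 2 tested members each, were not tested. Lists were tested with camera at a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The test of lists between extracts at 500 ug/mL was added after the data were seen. The fibroblast list, with 5 tested members, was not called for any extract at 500 ug/mL.

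Named genes at 500 ug/mL against the vehicle for the replicated extracts had adjusted p below 0.05, a mean of at least 5 CPM and every treated library on the same side of every vehicle library. The 6 largest rises and 6 largest falls were taken, leaving out clone names and antisense symbols. From each list with at least 3 members past the threshold, or called by camera, the 2 members with the smallest adjusted p were named, and every other comparison gave its 3 largest rises and 3 largest falls. CYP1A1, CYP1B1, HMOX1, NQO1, DDIT3, HMGCS1, CDKN1A, TXNIP, FKBP5, MKI67, CXCL8 and MT2A were fixed for every dose, and TXNIP had too few counts to be tested. LAMP3 was chosen after its values were seen. Some genes that meet the rule are not reported here.

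Alternatives were RLE size factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, replicate number as a block, a model with only the compared groups, each library left out in turn, and for lists a prior count of 0.5 and an estimated correlation. Leaving out 3 libraries, and leaving out each library for the shared sets, were added after the data were seen. Replicate numbers were checked for pairing over 10039 genes: in 15 comparisons the correlation of residuals between libraries of the same number ran from -0.443 to 0.32, and no comparison had every pair above 0.1, so the model has no block. In 24 pairs of libraries within groups chi-square per degree of freedom was 2.32 to 24.5, and no pair of columns was identical.

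The pipeline was tested on simulated data with 50 genes changed at each of 4 sizes. At 1.3, 1.5, 2 and 4-fold it recovered 62, 84, 92 and 100% for Bojungikgi-tang at 500 ug/mL against the vehicle, with 3.88% of calls false. For Banhasasim-tang it recovered 54, 84, 92 and 100% (4.06% false), and for Yijung-tang 48, 60, 88 and 100% (4.73% false). For Banhasasim-tang against Yijung-tang the shares were 30, 78, 86 and 98% (4.35% false), and for the difference of dose effects 52, 76, 94 and 98% (3.28% false). A planted mitotic list was called in each of these 5 runs, and 1 other list was called for Banhasasim-tang. Each gene had the same dispersion in every simulated library, so the lone Yijung-tang library varied like the others by construction. The shares above therefore do not cover the unequal spread of the real groups.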

Results

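RNA sequencing measured transcript abundance in A549 cells, a human non-small-cell lung carcinoma line with features of alveolar epithelium, after 24 h with ethanol extracts of 4 Korean herbal formulas traditionally given for digestive complaints. Bojungikgi-tang and Sayeok-tang were each represented by 3 libraries at 500, 100 and 20 ug/mL, Banhasasim-tang by 2 libraries per dose and Yijung-tang by 1 library per dose. The vehicle, dimethyl sulfoxide (DMSO), had 3 libraries, which makes 30 libraries in 13 groups. By general knowledge of these recipes, Banhasasim-tang contains Pinellia, Coptis and Scutellaria, Sayeok-tang aconite, ginger and licorice, Yijung-tang ginseng, ginger, licorice and Atractylodes, and Bojungikgi-tang astragalus and ginseng. The design asks which genes each dose of each extract changes relative to the vehicle, and the doses and extracts can also be compared with each other.

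Total expected counts per library ran from 18.48 to 36.47 M, with a median of 29.38 M, and 22356 to 24837 genes per library had counts. A total of 18227 genes had enough counts to be tested. On the first principal component, which held 37.7% of the variance, both Banhasasim-tang libraries at 500 ug/mL lay farthest from the vehicle. Replicate 1 of Bojungikgi-tang 500 ug/mL stood apart from its group on the second component, and its genes deviated from their group mean by an SD of 0.169 on the log2 scale, against 0.109 and 0.087 in the other replicates of that group. The comparable SD was 0.114 in Sayeok-tang 500 ug/mL replicate 3 and 0.091 in vehicle replicate 3.

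At 500 ug/mL, expression changed in 6785 genes with Banhasasim-tang, 5229 with Sayeok-tang, 3737 with Bojungikgi-tang and 1792 with Yijung-tang. Changes of at least 2-fold were found in 702, 285, 113 and 141 of these genes, in that order. The groups differ in size, and so the power to call a gene differs between extracts. With only the libraries of the compared groups in the model the order of doses turned round for Bojungikgi-tang, with 997 genes at 500 ug/mL and 2569 at 20 ug/mL. At 20 ug/mL the corresponding counts of changed genes were 1292, 1048, 1062 and 12.

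**Figure D1:**
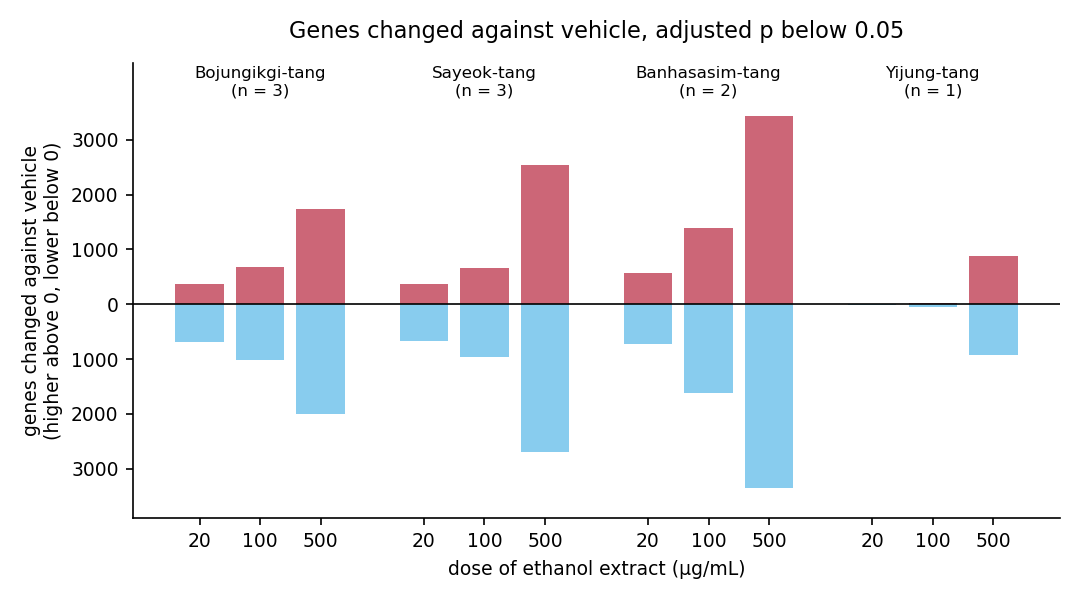
Number of genes that rose or fell against the vehicle at each dose in ug/mL for the 4 extracts. With all 30 libraries in the model, counts climbed from 20 to 500 ug/mL in every extract, up to 6785 genes with Banhasasim-tang.

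Bojungikgi-tang at 500 ug/mL raised AHR target and sterol-synthesis genes and lowered cell-cycle and heat shock genes. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610, GRCh38), a cytochrome P450 induced through AHR, the aryl hydrocarbon receptor, rose 7.57-fold, from 0.700 ± 0.23 to 5.26 ± 0.525 CPM (counts scaled to library size, mean ± SD, n = 3 in each group, adjusted p = 6.39e-11). CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902), regulated by the same receptor, rose 2.34-fold to 127.5 ± 21.3 CPM from 54.7 ± 1.73 (adjusted p = 6.39e-11). The orphan nuclear receptor genes NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891) and NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507), both immediate early genes, fell by 1.61 and 1.14 on the log2 scale (adjusted p = 2.06e-10 and 6.39e-11).

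Of 25 genes of cholesterol synthesis and uptake, 20 rose with Bojungikgi-tang at 500 ug/mL, and 21 when adjusted over the list alone (camera adjusted p = 7.62e-23). Among them, FDFT1, which makes squalene, rose from 118 ± 3.36 to 176.4 ± 5.71 CPM, and DHCR7, which makes cholesterol from its last precursor, rose by 0.71 on the log2 scale (SE 0.0452). HMGCS1, an early enzyme of the same pathway, did not pass the test (log2 fold change 0.14, adjusted p = 0.0695). Fatty acid synthesis genes rose as a list, with 7 of 14 higher and 1 lower (8 and 1 when adjusted over the list alone, camera adjusted p = 3.12e-07), including the desaturases FADS2 (0.63) and FADS1 (0.48). Of 25 targets of ATF4, the transcription factor of the integrated stress response, 17 rose, or 19 when adjusted over the list alone (camera adjusted p = 1.42e-11). TRIB3, a pseudokinase induced by ATF4, rose from 68.7 ± 1.18 to 117.7 ± 16.3 CPM and STC2, a secreted glycoprotein, by 0.65. DDIT3, which encodes the stress factor CHOP, changed by 0.25 with adjusted p = 0.0318, a call that was lost without vehicle replicate 1 (0.126), vehicle replicate 2 (0.0758) or treated replicate 1 (0.116).

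The AHR list followed CYP1A1 and CYP1B1 in Bojungikgi-tang at 500 ug/mL, with 6 of 9 targets higher both over all genes and when adjusted over the list alone (camera adjusted p = 7.74e-08). Mitotic genes fell: 21 of 30 were lower, or 22 when adjusted over the list alone (camera adjusted p = 2.29e-12), among them CDK1, the mitotic kinase (152.4 ± 6.44 to 112.3 ± 4.88 CPM), and its cyclin CCNB1. In the list of G1/S and DNA replication, 16 of 30 fell, 17 when adjusted over the list alone (camera adjusted p = 3.12e-07), including RRM2, a ribonucleotide reductase subunit (-0.36), and the replication clamp PCNA (-0.28). MKI67, a proliferation marker, did not pass (-0.05, adjusted p = 0.775). Of 20 heat shock genes 11 fell, or 12 when adjusted over the list alone (camera adjusted p = 7.23e-06), with DNAJB4, a co-chaperone, at -0.71 and HSPH1, a nucleotide exchange factor, at -0.39. The median of this list was -0.177 at 500 ug/mL and -0.159 at both 100 and 20 ug/mL, so its fall hardly depended on dose.

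Other genes with large rises with Bojungikgi-tang at 500 ug/mL were GREM1, an antagonist of bone morphogenetic proteins (2.25-fold, 11.2 ± 1.12 against 4.99 ± 0.252 CPM), CITED4, a transcriptional coactivator (log2 fold change 1.16), and RAP1GAP, which inactivates the GTPase RAP1 (1.01). CITED4 was already higher at 20 ug/mL, by 0.792 with Bojungikgi-tang, 0.768 with Sayeok-tang and 1.237 with Banhasasim-tang. The tetraspanin-like TM4SF4 and the planar polarity gene PRICKLE2 fell by 0.74 and 0.84 on the log2 scale. C4orf48 (1.75, adjusted p = 0.00147) varied widely between treated libraries (9.48 ± 6.24 CPM). RPL22P1, SMG1P1 and KRT86 were also called, but they share sequence with near-identical copies and are uncertain; SMG1P1 also lost its call without vehicle replicate 1 (0.0604).

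Secretory and alveolar type 2 genes rose as a list with Bojungikgi-tang at 500 ug/mL, with 5 of 9 higher and 1 lower (6 and 1 when adjusted over the list alone, camera adjusted p = 0.000944). The members that rose included ABCA3, a lipid transporter of lamellar bodies (0.33), and CEACAM6, a surface adhesion molecule (0.54). The surfactant genes SFTPB and SFTPC, the hallmark of these cells, had too few counts to be tested, so the list speaks for secretory genes more than for alveolar identity. The 13 mitochondrially encoded protein transcripts included 10 that rose, also when adjusted over the list alone (camera adjusted p = 5.69e-06), for example MT-CO2, a subunit of cytochrome c oxidase (0.55), although the list was not called with an estimated correlation (adjusted p = 0.221 with an estimated correlation). Their share of counts was 5.74% in the vehicle and already 7.27% with Bojungikgi-tang at 20 ug/mL, against 8.09% at 500 ug/mL. With Sayeok-tang the share was 6.85% at 20 ug/mL and 7.96% at 500 ug/mL. Immediate early and MAPK targets, with 6 higher and 2 lower of 22 (7 and 3 when adjusted over the list alone), reached camera adjusted p = 0.0494 but adjusted p = 0.166 with an estimated correlation. Their call also ended without vehicle replicate 1 (0.109), vehicle replicate 2 (0.08), treated replicate 2 (0.126) or treated replicate 3 (0.0544).

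Some lists that camera did not call with Bojungikgi-tang at 500 ug/mL still held members that changed. Among 26 NRF2 targets 6 rose and 2 fell (camera adjusted p = 0.372), with the autophagy receptor SQSTM1 at 0.43 and NQO1 at 0.05 (adjusted p = 0.569). Glucocorticoid receptor targets gave 2 higher and 5 lower of 20 (0.788), the kinase SGK1 at -0.61 and TSC22D3 at 0.53, while FKBP5 did not pass (0.03, adjusted p = 0.786). NF-kB and inflammatory genes gave 5 higher and 2 lower of 18 (0.0742), ER chaperone genes 2 and 2 of 20 (0.642), TGF-beta and matrix genes 1 higher and 9 lower of 23 (0.0515), and hypoxia and glycolysis genes 1 higher and 4 lower of 25 (0.176). The prostaglandin synthase PTGS2 fell by 0.67 on the log2 scale, the TGF-beta target PMEPA1 by 0.35 and the glucose transporter SLC2A3 by 0.69. Lysosome and autophagy genes gave 8 higher and 4 lower of 24 (0.164), fatty acid oxidation genes 4 and 2 of 16 (0.565), p53 targets 1 and 6 of 24 (0.47), and MondoA and FOXO genes 0 and 4 of 15 (0.192). Histone genes (1 higher, 1 lower of 14), ribosomal protein genes (4 higher of 28), interferon genes (1 and 1 of 18) the metallothioneins (1 lower of 5) and the xenobiotic metabolism list (1 higher of 10) were not called either.

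For Bojungikgi-tang at 500 ug/mL against the vehicle, edgeR's quasi-likelihood test called 1737 genes higher and 2000 lower with Benjamini-Hochberg adjustment, and 10 of 26 lists were called by camera, of which 8 held with an estimated correlation. The count was 2453 without vehicle replicate 2, and 997 when only the libraries of the compared groups entered the model.

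**Figure D2:**
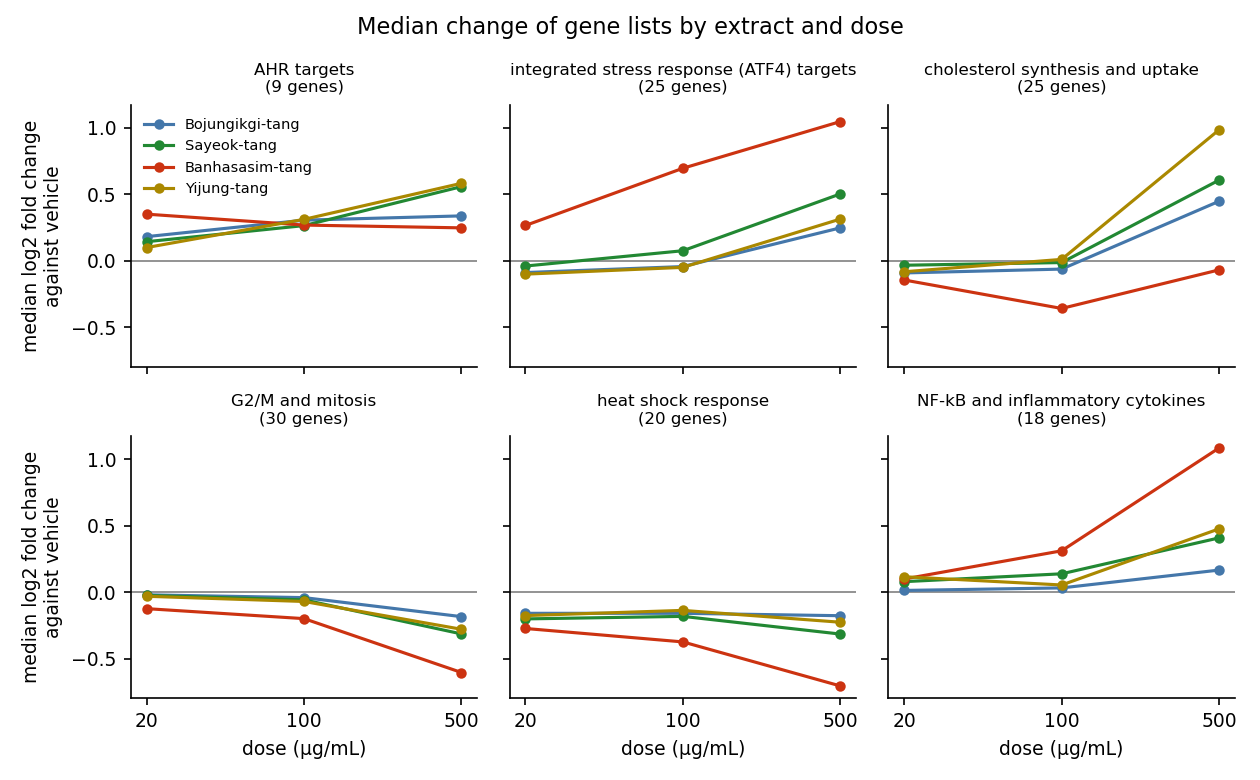
Median log2 fold change against the vehicle of the genes in 6 of the fixed lists at each dose in ug/mL, one line per extract. The ATF4 list reached 1.05 with Banhasasim-tang at 500 ug/mL, and the cholesterol list 0.99 with Yijung-tang.

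Sayeok-tang at 500 ug/mL raised sterol, fatty acid, ATF4 and inflammatory genes and lowered the cell-cycle and heat shock lists. NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550), a stress-induced regulator of translation, rose 3.75-fold to 39.7 ± 2.51 CPM from 10.5 ± 0.704 (n = 3 in each group, adjusted p = 2.82e-15). GREM1 (ENSG00000166923, chromosome 15, 32717974 to 32745107) rose 3.76-fold to 18.7 ± 0.836 CPM, and CDCP1 (ENSG00000163814, chromosome 3, 45082278 to 45146422), a transmembrane substrate of SRC kinases, 3.23-fold to 12.5 ± 0.903 CPM. The imprinted noncoding RNA H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470) fell from 82.0 ± 2.62 to 27.3 ± 1.08 CPM (log2 fold change -1.58, adjusted p = 7.63e-15), and FGB, which encodes the fibrinogen beta chain, from 157.8 ± 4.72 to 63.8 ± 3.67 CPM.

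Of the 25 cholesterol genes 23 rose and 1 fell with Sayeok-tang at 500 ug/mL (24 and 1 when adjusted over the list alone, camera adjusted p = 5.2e-26). DHCR7 rose by 0.98 on the log2 scale to 184.8 ± 5.55 CPM, FDFT1 by 0.77 and HMGCS1 by 0.31 (adjusted p = 0.00012). In fatty acid synthesis 10 of 14 genes rose, 11 when adjusted over the list alone (camera adjusted p = 4.21e-11). The stearoyl-CoA desaturase SCD rose from 927.4 ± 23.3 to 1977 ± 80.9 CPM, and FADS2 by 0.83. PLIN2, which coats lipid droplets, rose by 0.80.

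Of 25 ATF4 targets, 21 rose with Sayeok-tang at 500 ug/mL, also when adjusted over the list alone, where 1 fell (camera adjusted p = 1.26e-22). STC2 (ENSG00000113739, chromosome 5, 173314713 to 173329503) rose 2.54-fold to 72.9 ± 2.23 CPM from 28.6 ± 1.26 (adjusted p = 7.46e-17), TRIB3 rose by 1.33 and DDIT3 by 0.72 (adjusted p = 2.62e-07). ALDH1L2, a mitochondrial folate enzyme, rose by 1.41 (SE 0.097). Genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response rose in 11 of 20 cases and fell in 1 (14 and 1 when adjusted over the list alone, camera adjusted p = 2.64e-05), with the chaperone HYOU1 at 0.48 and the ubiquitin ligase SYVN1 at 0.54.

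Inflammatory NF-kB genes rose with Sayeok-tang at 500 ug/mL, with 13 of 18 higher and 1 lower (14 and 2 when adjusted over the list alone, camera adjusted p = 9.15e-06). The signalling kinase IRAK2 rose by 0.96, the cytokine LIF by 0.35 and the neutrophil chemokine CXCL8 by 1.17, to 2.25 ± 0.084 from 1.01 ± 0.17 CPM. Immediate early and MAPK targets gave 13 higher and 2 lower of 22 (14 and 2 when adjusted over the list alone, camera adjusted p = 0.00014), including ETV5 (0.35) and DUSP4 (0.33), both transcribed on ERK signalling. AHR targets gave 5 higher and 1 lower of 9, also when adjusted over the list alone (camera adjusted p = 0.000301), with CYP1A1 at 2.23, CYP1B1 at 1.26 and TIPARP, a feedback inhibitor of AHR, at 1.12. The member that fell was NQO1 (-0.22, adjusted p = 0.00249), a quinone reductase. In the alveolar and secretory list 4 of 9 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00245), with CEACAM6 at 0.63 and ABCA3 at 0.44.

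Cell-cycle genes fell with Sayeok-tang at 500 ug/mL, in 25 of 30 mitotic genes (27 when adjusted over the list alone, camera adjusted p = 5.84e-21) and 24 of 30 G1/S genes (25 when adjusted over the list alone, camera adjusted p = 6.23e-14). CDK1 fell by 0.61 on the log2 scale, CCNB1 by 0.55, RRM2 by 0.47 and the replication factor GINS1 by 0.45, while MKI67 did not pass (-0.17, adjusted p = 0.194). In the heat shock list 15 of 20 fell, also when adjusted over the list alone (camera adjusted p = 1.17e-09), with DNAJB4 at -0.85 and DNAJA1 at -0.53. Hypoxia and glycolysis genes gave 6 higher and 10 lower of 25 (6 and 11 when adjusted over the list alone, camera adjusted p = 0.0387), with SLC2A3 at -0.88 and the peptide hormone gene ADM at -0.55; this call ended without vehicle replicate 3 (0.0629) or treated replicate 2 (0.0526). Mitochondrial protein transcripts rose in 8 of 13 cases (10 when adjusted over the list alone, camera adjusted p = 0.000342, adjusted p = 0.352 with an estimated correlation). Ribosomal protein genes gave 1 higher and 7 lower of 28 (1 and 8 when adjusted over the list alone, camera adjusted p = 0.0387, adjusted p = 0.754 with an estimated correlation), a call lost without vehicle replicate 3 (0.251) or treated replicate 3 (0.518).

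NRF2 targets split with Sayeok-tang at 500 ug/mL, with 6 higher and 12 lower of 26 (camera adjusted p = 0.102): the heme oxygenase HMOX1 rose by 0.41 and SQSTM1 by 0.47, and the glutathione peroxidase GPX2 fell by 0.85. TSC22D3 rose by 0.94 and SGK1 fell by 0.69, both glucocorticoid-regulated. Among p53 targets 6 rose and 2 fell of 24, with the cytokine GDF15 at 0.60, the death receptor TNFRSF10B at 0.37 and the cell-cycle inhibitor CDKN1A at 0.14 (adjusted p = 0.00925). The TGF-beta list had 6 higher and 6 lower members of 23. NR4A3 and NR4A1 fell by 1.84 and 1.33 on the log2 scale, and INSL4, a relaxin-family hormone, by 1.25. EIF3CL (2.79, adjusted p = 0.0306, 41.2 ± 29.6 against 5.49 ± 4.13 CPM) has a near-identical paralog and is uncertain, and its call ended without vehicle replicate 1 (0.0741), 2 (0.0534) or 3 (0.102) or treated replicate 3 (0.185).

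For Sayeok-tang at 500 ug/mL against the vehicle, edgeR's test called 2538 genes higher and 2691 lower, and 14 of 26 lists were called by camera, of which 12 held with an estimated correlation. Leaving out any 1 of the 6 libraries gave between 4022 and 4974 genes.

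Banhasasim-tang at 500 ug/mL gave the largest counts, with mitochondrial ribosomal RNA, ATF4 targets and inflammatory genes higher and cell-cycle and heat shock genes lower. MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601), the small mitochondrial rRNA, rose 29.6-fold to 44600 ± 1860 CPM (n = 2) from 1508 ± 104 (n = 3, adjusted p = 1.15e-20). MT-RNR2 (ENSG00000210082, 1671 to 3229), the large one, rose 5.64-fold to 115100 ± 9640 from 20400 ± 831 CPM (adjusted p = 4.97e-16). NIBAN1 rose 9.65-fold to 102.1 ± 3.3 CPM (adjusted p = 1.15e-20), and the stress chaperone gene HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) fell from 337.5 ± 15.4 to 91.9 ± 5.05 CPM (log2 fold change -1.88, adjusted p = 1.4e-15).

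Both mitochondrial rRNAs together held 14.5% of all counts in Banhasasim-tang at 500 ug/mL (SD 0.799), 11.02% at 100 ug/mL (SD 0.092) and 3.55% at 20 ug/mL (SD 0.098), against 2.24% in the vehicle (SD 0.091). In the other extracts the share lay between 2.77 and 3.15% at every dose. MT-RNR1 also rose at 100 ug/mL (log2 fold change 4.51, adjusted p = 1.12e-19, 34310 ± 203 CPM) and at 20 ug/mL (2.12, adjusted p = 1.27e-12, 6547 ± 199 CPM). The 13 protein-coding mitochondrial transcripts went both ways at 500 ug/mL, with 3 higher and 5 lower (camera adjusted p = 0.757). MT-CYB, a cytochrome bc1 subunit, rose by 1.49 (10290 ± 244 against 3657 ± 505 CPM), MT-ND5 by 1.17 and MT-ND6 by 1.43, whereas MT-CO3 fell by 0.66 and MT-ND4L by 0.69. At 100 ug/mL MT-ND5 rose by 2.88 to 18940 ± 252 from 2563 ± 226 CPM, MT-ND2 by 1.66 and MT-ND1 by 1.25, and MT-CO3 fell by 0.90. MT-ND5 and MT-ND6 lie on opposite strands next to MT-CYB, and whether counting used strand is not given in the sources used here, so their separate values are uncertain.

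**Figure D3:**
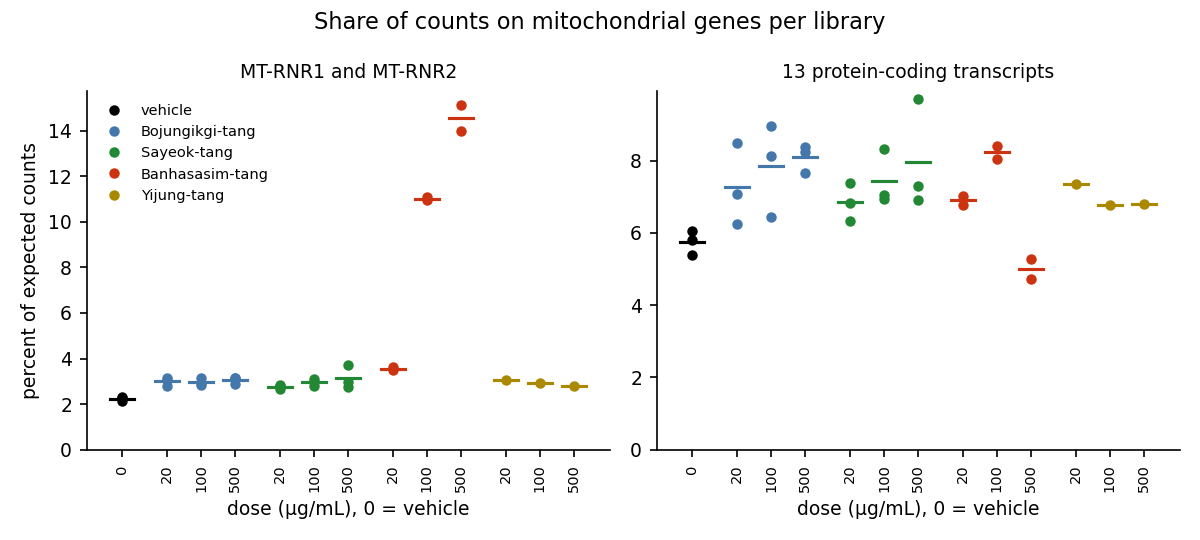
Share of all counts (percent, linear axis) taken by the mitochondrial rRNAs MT-RNR1 and MT-RNR2 and, in the second panel, by the 13 mitochondrial protein-coding transcripts in each library, by dose in ug/mL. The rRNA share averaged 14.5% in Banhasasim-tang at 500 ug/mL and 2.24% in the vehicle.

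**Figure D4:**
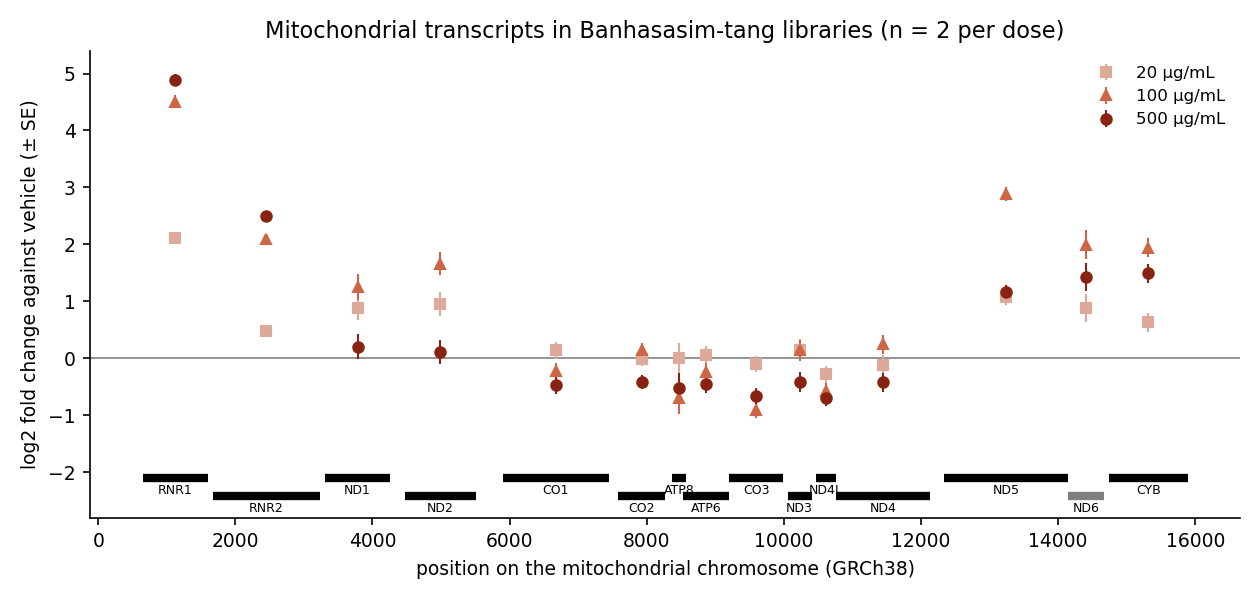
Map of the mitochondrial genome (position in bp, GRCh38) with the log2 fold change of each tested transcript for Banhasasim-tang against the vehicle. MT-RNR1, at 648 to 1601, had the largest rise, 4.89 at 500 ug/mL.

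Of 25 ATF4 targets 23 rose with Banhasasim-tang at 500 ug/mL, also when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 7.12e-29). STC2 rose 5.31-fold to 152.3 ± 2.81 CPM (adjusted p = 2.09e-22), TRIB3 by 2.25 on the log2 scale to 326.6 ± 2.53 CPM, DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) 4.5-fold to 44.4 ± 1.32 CPM from 9.87 ± 0.526 (adjusted p = 1.94e-16), and ADM2 (ENSG00000128165, chromosome 22, 50481556 to 50486440), a peptide hormone of the calcitonin family, 8.25-fold to 12.4 ± 0.708 CPM. ER chaperone genes were not called as a list (7 higher and 3 lower of 20, camera adjusted p = 0.156), although HYOU1 rose by 0.82 and the transcription factor XBP1 by 0.81.

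Inflammatory genes rose in 15 of 18 cases with Banhasasim-tang at 500 ug/mL, also when adjusted over the list alone (median 1.08, camera adjusted p = 7.65e-10). CXCL8 rose 5.0-fold to 5.03 ± 1.02 CPM, IRAK2 by 1.60 and the chemokine CXCL5 by 1.16. MAPK and immediate early targets rose in 18 of 22 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 3.68e-11), led by the growth factor EREG (350.7 ± 18.2 against 161.4 ± 0.61 CPM). In the p53 list 14 of 24 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 2.97e-05), with TNFRSF10B at 0.91 and CDKN1A at 192.5 ± 9.79 against 110.7 ± 3.55 CPM. AHR targets gave 4 higher and 1 lower of 9 (5 and 2 when adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.141 with an estimated correlation), with CYP1A1 at 1.56, CYP1B1 at 1.01 and TIPARP at 1.11.

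Cell-cycle genes were lower in most of both lists with Banhasasim-tang at 500 ug/mL: 30 of 30 mitotic genes (camera adjusted p = 8.76e-29) and 28 of 30 G1/S genes (camera adjusted p = 1.2e-22) fell, also when adjusted over the list alone. RRM2 fell from 332.9 ± 5.65 to 166.3 ± 1.27 CPM, MKI67 from 498.1 ± 57.4 to 299.3 ± 9.66 CPM, CCNA2 by 0.79 on the log2 scale, the mitotic kinesin KIF11 by 0.88, and the inhibitor gene CDKN2C by 1.53. Heat shock genes fell in 18 of 20 cases, also when adjusted over the list alone (camera adjusted p = 2.62e-19). HSPA1B fell by 1.66 to 61.5 ± 0.172 from 194.8 ± 5.96 CPM, and because it is nearly identical to HSPA1A the split between them is uncertain.

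In the cholesterol list 3 of 25 genes rose and 7 fell with Banhasasim-tang at 500 ug/mL (3 and 8 when adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.345 with an estimated correlation). IDI1, an isomerase of the pathway, fell by 0.58 on the log2 scale and HMGCS1 by 0.45 (adjusted p = 2.21e-06). Fatty acid synthesis genes were not called (3 higher and 5 lower of 14, camera adjusted p = 0.936). TGF-beta and matrix genes gave 10 higher and 2 lower of 23, also when adjusted over the list alone (camera adjusted p = 0.00917, adjusted p = 0.226 with an estimated correlation). Ribosomal protein genes gave 13 higher of 28, also when adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.561 with an estimated correlation), for example RPS27 (0.49).

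Among 9 alveolar and secretory genes 5 rose and 1 fell with Banhasasim-tang at 500 ug/mL, also when adjusted over the list alone (camera adjusted p = 0.0151). ETV5 rose by 0.75, ABCA3 by 0.70 and LAMP3, a lysosomal membrane protein singled out after its values were seen, by 4.24 (SE 0.415, adjusted p = 1.14e-08). NRF2 targets again split, with 5 higher and 12 lower of 26 (camera adjusted p = 0.199), the export pump ABCC3 at 0.97, HMOX1 at 0.29 and NQO1 not passing (-0.13, adjusted p = 0.0856). Hypoxia genes gave 6 higher and 10 lower of 25 (camera adjusted p = 0.104), with the angiogenic factor VEGFA at 0.89 and SLC2A3 at -0.77. TSC22D3 rose by 1.90 and SGK1 fell by 0.84, while FKBP5 (adjusted p = 0.137) and the metallothionein MT2A (adjusted p = 0.827) did not pass. Interferon genes gave 3 higher and 1 lower of 18, with STAT2 at 0.39 and OAS1 at -0.49, and xenobiotic metabolism genes 1 higher and 3 lower of 10, with the carboxylesterase CES2 at 0.26 and the efflux pump ABCG2 at -0.48. CDCP1 rose 5.49-fold to 21.2 ± 1.94 CPM, and H19 and BCAS1 fell by 1.87 and 1.51 on the log2 scale.

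For Banhasasim-tang at 500 ug/mL against the vehicle, edgeR's test called 3437 genes higher and 3348 lower with n = 2 against 3, and 12 of 26 lists were called by camera, of which 8 held with an estimated correlation. CXCR5 (2.46, adjusted p = 0.0385) varied widely between libraries and lost its call without vehicle replicate 1 (0.143), vehicle replicate 2 (0.0962), treated replicate 2 (0.219) or treated replicate 3 (0.0515), and the histone gene H4C3 (1.57, adjusted p = 0.00208) without treated replicate 2 (0.153).

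Yijung-tang at 500 ug/mL was measured in 1 library, so the difference has no replicate check, and the lone library was assumed to vary like the other groups. Its largest list change was in cholesterol genes, of which 24 of 25 were higher, also when adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.29e-57). HMGCS1 was at 338.8 CPM against 200 ± 5.52 in the vehicle (log2 fold change 0.76, SE 0.0733, adjusted p = 7.94e-08). Fatty acid synthesis genes were higher in 10 of 14 cases, or 12 when adjusted over the list alone (camera adjusted p = 3.07e-19).

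ATF4 targets were higher in 16 of 25 cases in Yijung-tang at 500 ug/mL (18 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.1e-15), with DDIT3 at 0.63. Inflammatory genes gave 9 higher and 1 lower of 18 (14 and 1 when adjusted over the list alone, camera adjusted p = 2.94e-08), with CXCL8 at 1.23. AHR targets gave 5 of 9 higher, also when adjusted over the list alone (camera adjusted p = 9.5e-07), with CYP1A1 at 2.25 and CYP1B1 at 134.9 against 54.7 ± 1.73 CPM. Mitotic genes were lower in 23 of 30 cases, also when adjusted over the list alone (camera adjusted p = 6.16e-21), G1/S genes in 10 of 30 (13 when adjusted over the list alone, camera adjusted p = 1.59e-09) and heat shock genes in 10 of 20 (12 when adjusted over the list alone, camera adjusted p = 1.1e-07). MKI67 (0.05), CDKN1A (-0.03), HMOX1 (0.16), NQO1 (-0.09), MT2A (-0.02) and FKBP5 (-0.01) did not pass. ER chaperone genes (5 of 20 higher, 10 when adjusted over the list alone, camera adjusted p = 4.58e-05), MAPK targets (6 of 22, 10 when adjusted over the list alone, camera adjusted p = 0.000887) and alveolar genes (4 of 9, 6 when adjusted over the list alone, camera adjusted p = 0.000342) were higher. So were lysosome and autophagy genes, with 9 higher and 1 lower of 24 (13 and 3 when adjusted over the list alone, camera adjusted p = 0.000887).

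Calls for p53 targets (camera adjusted p = 0.0347), TGF-beta and matrix genes (0.0393) and ribosomal protein genes (0.0164) in Yijung-tang at 500 ug/mL were lost with an estimated correlation (adjusted p = 0.142, 0.291 and 0.613 with an estimated correlation). Camera called all 3 lists down, with a median of -0.182 for p53 targets although more of them passed as higher than as lower. The p53 list had 2 higher and 1 lower of 24, the TGF-beta list 2 and 5 of 23, and the ribosomal list 0 and 2 of 28 (2 and 4, 3 and 8, and 0 and 2 when adjusted over the list alone). They were also lost without vehicle replicate 3 for the p53 (0.0886) and ribosomal lists (0.126) and without vehicle replicate 1 (0.0682) or 2 (0.0558) for the TGF-beta list. GREM1 was higher by 1.54 and NR4A3 and TM4SF4 lower (-1.67 and -1.19), and KRT86 (-1.47) and EIF3CL (3.59) share sequence with other genes and are uncertain. EIF3CL lost its call without vehicle replicate 1 (0.0806), 2 (0.0661) or 3 (0.104). In all, edgeR's test called 873 genes higher and 919 lower, and 15 of 26 lists were called, of which 12 held with an estimated correlation.

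At 100 and 20 ug/mL AHR targets and heat shock genes were among the lists that moved with several extracts. Ribosomal protein genes had medians of -0.131 and -0.169 with Bojungikgi-tang, -0.169 and -0.173 with Sayeok-tang and -0.001 and -0.11 with Banhasasim-tang at these doses. CYP1A1 and CYP1B1 rose at both lower doses of the 3 replicated extracts, by 1.92 and 0.93 with Bojungikgi-tang, 1.90 and 0.90 with Sayeok-tang and 1.91 and 0.96 with Banhasasim-tang at 100 ug/mL. At 20 ug/mL the changes in CYP1A1 were 1.01 (adjusted p = 0.00654), 1.01 (0.00717) and 1.98 (1.31e-06) in the same order, and without vehicle replicate 2 the first was not called (0.0904), nor the second (0.0941). In the lone Yijung-tang libraries CYP1A1 was higher at 100 ug/mL (1.48, adjusted p = 0.00988) and did not pass at 20 ug/mL (0.80, adjusted p = 0.312). Heat shock genes fell in 12 and 10 of 20 cases with Bojungikgi-tang at 100 and 20 ug/mL (13 and 12 when adjusted over the list alone), in 11 and 12 with Sayeok-tang (13 and 15 when adjusted over the list alone) and in 16 and 13 with Banhasasim-tang (16 and 16 when adjusted over the list alone). The heat shock median at 20 ug/mL was -0.159 with Bojungikgi-tang, -0.201 with Sayeok-tang, -0.273 with Banhasasim-tang and -0.176 in the lone Yijung-tang library. At 500 ug/mL it was -0.177, -0.315, -0.705 and -0.226 in the same order. The heat shock calls of the replicated extracts at 100 and 20 ug/mL held with an estimated correlation (adjusted p from 0.000138 to 0.0462 with an estimated correlation). The AHR calls for Bojungikgi-tang and Yijung-tang at 20 ug/mL did not (adjusted p = 0.075 and 0.182 with an estimated correlation). Camera called 10 and 12 lists at 100 and 20 ug/mL with Bojungikgi-tang, of which 2 and 1 held with an estimated correlation. It called 9 and 9 with Sayeok-tang (2 and 5 held), 11 and 12 with Banhasasim-tang (9 and 7 held) and 10 and 9 with Yijung-tang, where 2 held at 100 ug/mL and those at 20 ug/mL were all lost.

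Banhasasim-tang at 100 ug/mL changed ATF4 and sterol genes in opposite directions. ATF4 targets rose in 23 of 25 cases, 24 when adjusted over the list alone (camera adjusted p = 6.75e-41), with DDIT3 at 0.87 (adjusted p = 1.51e-07), and 21 of 25 cholesterol genes fell, 22 when adjusted over the list alone (median -0.36, camera adjusted p = 4.14e-20), with HMGCS1 at -0.56 (adjusted p = 8.23e-07). Mitotic genes fell in 22 of 30 cases (23 when adjusted over the list alone, camera adjusted p = 1.71e-15) and HSPA1A by 0.98 on the log2 scale. At 20 ug/mL ATF4 targets rose in 14 of 25 cases (17 when adjusted over the list alone, camera adjusted p = 2.24e-16), and cholesterol genes fell in 7 of 25 (10 lower and 1 higher when adjusted over the list alone, camera adjusted p = 7.39e-06). HMGCS1 fell by 0.33 (adjusted p = 0.00288) and was not called without treated replicate 2 (0.129).

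With Sayeok-tang, GREM1 rose by 0.98 on the log2 scale at 100 ug/mL, and at 20 ug/mL ZNF580, a zinc finger gene, rose by 0.72 and ANKRD18A by 0.68. Neither rise was particular to Sayeok-tang. At 20 ug/mL ZNF580 rose by 0.706 with Bojungikgi-tang and 0.913 with Banhasasim-tang, and ANKRD18A by 0.604 and 0.628. ARL6IP6, named below for Yijung-tang, also fell at 20 ug/mL with Bojungikgi-tang (-0.596), Sayeok-tang (-0.545) and Banhasasim-tang (-0.408). HMOX1 fell with Sayeok-tang at 20 ug/mL (-0.31, adjusted p = 0.00525). MKI67 was called higher at 20 ug/mL with Bojungikgi-tang and Sayeok-tang, but not without vehicle replicate 3 (log2 fold change then 0.294 and 0.292). With Bojungikgi-tang at 20 ug/mL HMOX1, HMGCS1, CDKN1A and MT2A were called lower. Each lost its call without vehicle replicate 3 (then -0.247, -0.219, -0.107 and -0.296). NR4A3 fell at 100 ug/mL with Bojungikgi-tang (-0.80) and Banhasasim-tang (-1.03). KRT86, uncertain for its many keratin relatives, was lower in most of these comparisons, for example by 1.19 with Bojungikgi-tang at 20 ug/mL. The lone Yijung-tang library at 20 ug/mL differed from the vehicle in 12 genes, including SREBF1, a regulator of lipid synthesis (0.29, adjusted p = 0.0125), and ARL6IP6 (-0.55, adjusted p = 0.00781). The one at 100 ug/mL differed in 71 genes, including CACNG8 (0.58).

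Counts at the lower doses were 1694 and 1062 genes for Bojungikgi-tang, 1632 and 1048 for Sayeok-tang and 3013 and 1292 for Banhasasim-tang at 100 and 20 ug/mL, by edgeR's test. They depended on single libraries: leaving 1 out gave 325 to 698 genes for Bojungikgi-tang at 20 ug/mL whichever of the 6 it was, 679 to 1118 at 100 ug/mL for any library other than treated replicate 1, 682 to 936 for Sayeok-tang at 100 ug/mL and 301 to 453 at 20 ug/mL for any library other than vehicle replicate 1, and 1365 or 1242 for Banhasasim-tang at 100 ug/mL without treated replicate 2 or 3. At 20 ug/mL Banhasasim-tang gave 86 genes without treated replicate 2, 543 without treated replicate 3, 558 without vehicle replicate 2 and 724 without vehicle replicate 3. Yijung-tang gave 35, 23 and 12 genes at 100 ug/mL without vehicle replicates 1, 2 and 3, and 5 genes at 20 ug/mL without vehicle replicate 2. Of the genes called at 20 ug/mL, 513 were called in all 3 replicated extracts, 164 higher and 349 lower. Independent lists would share 0.23 and 1.04. A total of 20 simulated draws with shared vehicle libraries and no true change called an average of 0.1 genes per extract. These draws held no difference common to the vehicle libraries. The shared set depends on single libraries too: leaving out any 1 of the 11 libraries gave 51 to 341 genes, the fewest without Banhasasim-tang replicate 2 and the most without vehicle replicate 1.

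The contrast of 500 with 20 ug/mL within an extract uses no vehicle library. For Yijung-tang it sets 1 library against 1, with no replicate in either arm, so its p-values rest wholly on the spread of the other groups. Cholesterol genes rose between these doses in 21 of 25 cases with Bojungikgi-tang (24 when adjusted over the list alone, camera adjusted p = 1.44e-40) and in 24 of 25 with Sayeok-tang, also when adjusted over the list alone (camera adjusted p = 3.45e-44). In the Yijung-tang libraries 24 of 25 were higher, also when adjusted over the list alone (camera adjusted p = 1.26e-102), for example MSMO1, a sterol oxidase (100.0 against 37.0 CPM), and INSIG1, a sterol sensor (83.6 against 32.04 CPM). ATF4 targets rose in 18, 20, 21 and 15 of 25 cases with Bojungikgi-tang, Sayeok-tang, Banhasasim-tang and Yijung-tang (20, 20, 21 and 18 when adjusted over the list alone, where 1 also fell with Banhasasim-tang), with medians of 0.31, 0.61, 0.88 and 0.42 and camera adjusted p of 5.39e-25, 3.93e-38, 1.08e-33 and 1.71e-30.

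Yijung-tang values between 20 and 500 ug/mL again come from 1 library against 1. Mitotic genes fell between these doses in 19 of 30 cases with Bojungikgi-tang (22 when adjusted over the list alone, camera adjusted p = 6.31e-14), 29 of 30 with Sayeok-tang, also when adjusted over the list alone (camera adjusted p = 8.45e-30), 29 of 30 with Banhasasim-tang, also when adjusted over the list alone (camera adjusted p = 1.08e-33), and 3 of 30 with Yijung-tang (24 when adjusted over the list alone, camera adjusted p = 2.35e-25). Inflammatory genes rose in 14 of 18 cases with Banhasasim-tang (15 higher and 1 lower when adjusted over the list alone, camera adjusted p = 2.42e-12) and in 9 of 18 with Sayeok-tang, where 1 fell (12 and 1 when adjusted over the list alone, camera adjusted p = 7.99e-06). Targets of p53 rose in 17 of 24 cases with Banhasasim-tang, where 1 fell (18 and 1 when adjusted over the list alone, camera adjusted p = 9.41e-12). Heat shock genes fell in 16 of 20 cases with Banhasasim-tang, also when adjusted over the list alone (camera adjusted p = 3.22e-17). In these contrasts camera called 12, 16, 11 and 13 lists with Bojungikgi-tang, Sayeok-tang, Banhasasim-tang and Yijung-tang, of which 5, 9, 8 and 10 held with an estimated correlation. The alveolar list in Yijung-tang had a median of -0.001 and a mean of 0.193, with camera's direction up (adjusted p = 0.0297, adjusted p = 0.0655 with an estimated correlation).

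Single genes with large differences between the doses were NIBAN1, which rose by 1.65 with Sayeok-tang and 2.71 with Banhasasim-tang, and H19, which fell by 1.55 and 1.78 on the log2 scale. TRIB3 rose by 0.92 with Bojungikgi-tang and 1.35 with Sayeok-tang, and RNF43, a ubiquitin ligase acting on Wnt receptors, was lower in both (-0.94 and -1.26). The number of genes that differed between 500 and 20 ug/mL was 1797 for Bojungikgi-tang, 2569 for Sayeok-tang and 4269 for Banhasasim-tang. Between the lone Yijung-tang libraries, with no replicate in either arm, 248 genes were called. The Bojungikgi-tang count was 725 without replicate 1 at 500 ug/mL, 3214 without replicate 2 at 500 ug/mL, 1115, 916 and 668 without replicates 1, 2 and 3 at 20 ug/mL, and 142 when only its own libraries entered the model. That for Banhasasim-tang was 2739 without replicate 2 and 2837 without replicate 3 at 500 ug/mL, and 2810 without replicate 2 at 20 ug/mL.

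Responses to dose overlapped between extracts, which share no library in these contrasts. Bojungikgi-tang and Sayeok-tang had 936 genes called in both, of which 471 were higher and 464 lower in both, where independent lists would give 64.3 and 61.9. The overlap was 509 genes without Bojungikgi-tang replicate 3 at 20 ug/mL, and 133 when each extract was modelled with only its own libraries. Sayeok-tang and Banhasasim-tang had 1770 in common, with 98.6% of the same sign, and Bojungikgi-tang and Banhasasim-tang 936, with 94.9% of the same sign and 48 of opposite sign. Yijung-tang, with 1 library per dose, shared 191 genes with Bojungikgi-tang, 237 with Sayeok-tang and 184 with Banhasasim-tang. Over all tested genes, called or not, the correlation of the log2 changes was low. It was 0.243 for Bojungikgi-tang and Sayeok-tang, 0.283 for Sayeok-tang and Banhasasim-tang, and 0.226 for Bojungikgi-tang and Banhasasim-tang. For Yijung-tang it was 0.057, 0.16 and 0.114 with Bojungikgi-tang, Sayeok-tang and Banhasasim-tang.

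At the matched dose of 500 ug/mL Banhasasim-tang was compared with each other extract, and Bojungikgi-tang with Sayeok-tang. Cholesterol genes were lower with Banhasasim-tang than with Bojungikgi-tang in 22 of 25 cases (camera adjusted p = 1.62e-23), than with Sayeok-tang in 24 (5.01e-48) and than with Yijung-tang in 24 (5.56e-59). ATF4 targets were higher with Banhasasim-tang in 22, 22 and 21 of 25 cases against the same extracts (2.18e-32, 9.72e-32 and 7.05e-41), and heat shock genes lower in 16, 16 and 15 of 20 (2.47e-21, 7.02e-24 and 6.81e-23). Inflammatory genes were higher in 16 of 18 cases than with Bojungikgi-tang, where 1 was lower (1.24e-11), and p53 targets in 16 of 24, where 1 was lower (2.7e-10). These list calls between extracts held with an estimated correlation.

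At 500 ug/mL MT-RNR1 was higher with Banhasasim-tang by 4.45, 4.67 and 4.70 on the log2 scale than with Bojungikgi-tang, Sayeok-tang and Yijung-tang (adjusted p = 7.28e-20, 5.44e-20 and 2.33e-15). SLFN5, an interferon-inducible nuclear protein, was at 78.6 ± 2.06 CPM with Banhasasim-tang and 18.3 ± 2.39 with Bojungikgi-tang (adjusted p = 4.78e-16). BEX2 was higher with Banhasasim-tang than in the lone Yijung-tang library by 2.42. HSPA1A was lower than with Bojungikgi-tang (-1.69), Sayeok-tang (-1.43) and Yijung-tang (-1.54).

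Bojungikgi-tang differed from Sayeok-tang at 500 ug/mL in several lists. The ER chaperone and inflammatory lists were called against the vehicle for Sayeok-tang and not for Bojungikgi-tang. ATF4 targets were lower with Bojungikgi-tang in 18 of 25 cases (camera adjusted p = 2.16e-22), ER chaperone genes in 12 of 20 (1.53e-11), cholesterol genes in 14 of 25 (6.68e-12) and inflammatory genes in 3 of 18 (1.23e-05), and mitotic genes were higher in 11 of 30 (4.05e-13). H19 was at 60.7 ± 6.34 CPM with Bojungikgi-tang and 27.3 ± 1.08 with Sayeok-tang (adjusted p = 3.76e-11), and the keratin gene KRT4 was higher by 1.05. NIBAN1, CDCP1 and ALDH1L2 were lower with Bojungikgi-tang (-1.09, -0.92 and -0.91). ZACN, a zinc-activated channel, was higher by 1.10 (adjusted p = 0.0115), a call lost without Bojungikgi-tang replicate 1 (0.0892) or Sayeok-tang replicate 3 (0.0618).

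By edgeR's test 4810 genes differed between Banhasasim-tang and Bojungikgi-tang, 2653 between Banhasasim-tang and Sayeok-tang, 2089 between Banhasasim-tang and Yijung-tang and 1419 between Bojungikgi-tang and Sayeok-tang. Without Banhasasim-tang replicate 2 or 3 the first 3 counts were 3107 or 2932, 1286 or 1316, and 1321 or 1364. The last was 672 without Bojungikgi-tang replicate 1, 2655 without its replicate 2, 912 without Sayeok-tang replicate 3 and 14 when only the libraries of both groups entered the model.

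**Figure D5:**
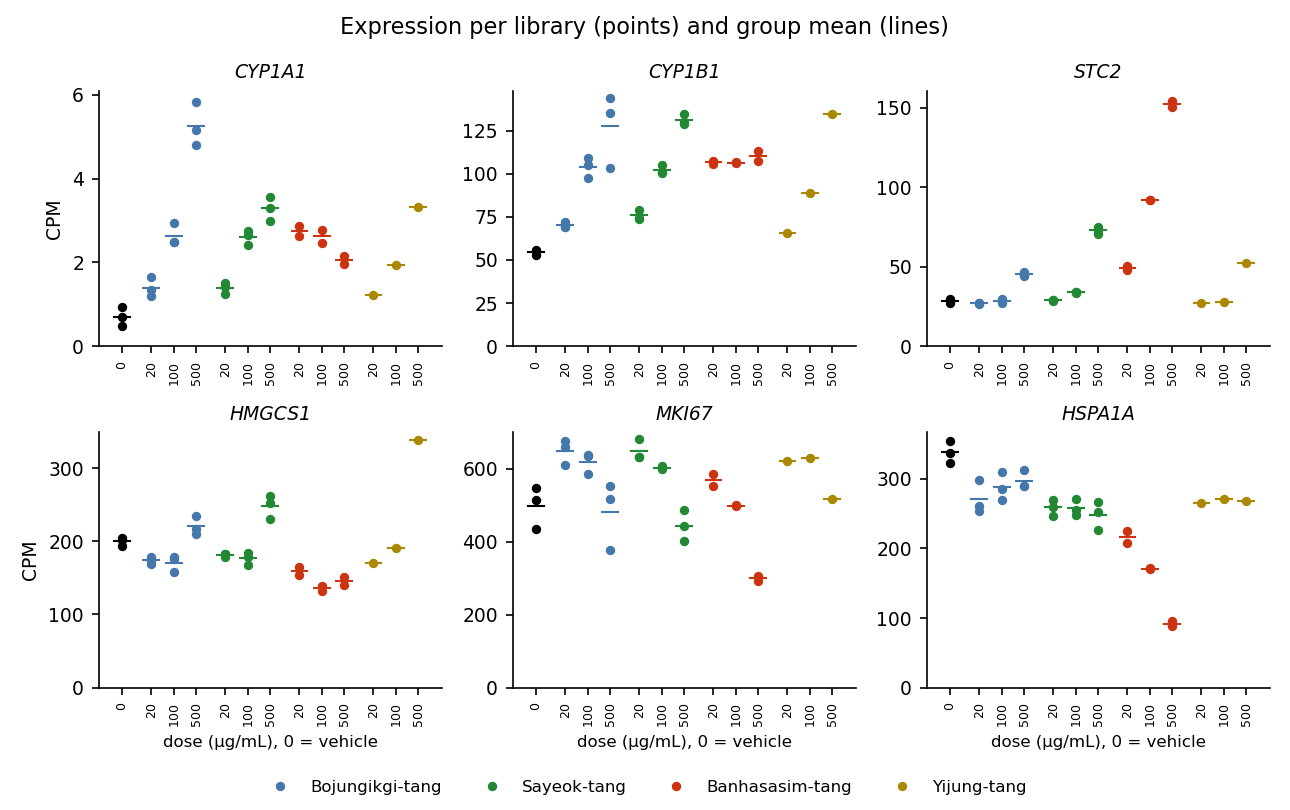
Normalised expression (CPM) of 6 genes in each of the 30 libraries, one point per library with group means as lines, by dose in ug/mL. CYP1A1 averaged 0.700 CPM in the vehicle and 5.26 CPM in Bojungikgi-tang at 500 ug/mL.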

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

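The genes below were found by a test of the difference of dose effects that was planned, and no further tests were chosen only after the result was seen.

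The change between 20 and 500 ug/mL differed between Bojungikgi-tang and Sayeok-tang for 135 genes. Leaving out 1 library gave 50 to 275 genes, and only the libraries of the compared groups 13. Subtracting the Sayeok-tang effect from the Bojungikgi-tang effect, the difference was 1.01 for H19 (adjusted p = 3.69e-07), 0.952 for KRT4 (3.69e-07) and 0.826 for NECAB2, a calcium-binding protein (0.00925). It was -0.959 for NIBAN1 (9.79e-06), -0.849 for CDCP1 (0.00169) and -0.799 for ALDH1L2 (0.00411). H19 changed by -0.538 with Bojungikgi-tang and -1.548 with Sayeok-tang, and NIBAN1 by 0.687 and 1.646, and in each of the 6 genes named here both effects had the same sign.

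Chance is not excluded as the source of the 135 genes. Of 100 regroupings of the same libraries, the real one included, 7 called as many genes, and the highest other called 434. Libraries were exchanged between the extracts separately at 500 and at 20 ug/mL. A regrouping could therefore keep the extracts apart at 500 ug/mL, where 1419 genes differed between them. Such regroupings carry that difference, so these numbers cannot decide whether the 135 genes arose by chance. Replicate 1 of Bojungikgi-tang at 500 ug/mL stood apart from its group.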

How the results depend on the processing

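With no filter on low counts the number of changed genes was 1653 for Sayeok-tang at 20 ug/mL (1048 in the chosen analysis), 493 (71) and 306 (12) for Yijung-tang at 100 and 20 ug/mL, and 382 (135) for the difference of dose effects. DESeq2 gave 262 and 89 for Yijung-tang at 100 and 20 ug/mL. With replicate as a block Yijung-tang at 100 ug/mL gave 24. RLE size factors and the filter of at least 1 CPM left all 21 counts within 1.5 times.

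With only the libraries of the compared groups the counts were 997 for Bojungikgi-tang at 500 ug/mL and 2569 at 20 ug/mL, 3075 and 2684 for Sayeok-tang at 100 and 20 ug/mL, 2101 for Banhasasim-tang at 20 ug/mL, and 358 and 114 for Yijung-tang at 100 and 20 ug/mL. They were 142 for Bojungikgi-tang 500 against 20 ug/mL, 14 for Bojungikgi-tang against Sayeok-tang, 1660 and 4798 for Banhasasim-tang against Bojungikgi-tang and Yijung-tang, and 13 for the difference of dose effects. Yijung-tang 500 against 20 ug/mL has no value, as no residual degree of freedom is left.

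Leaving out 3 libraries that stand apart, chosen after seeing the data (Bojungikgi-tang 500 ug/mL replicate 1, Sayeok-tang 500 ug/mL replicate 3 and vehicle replicate 3), gave 1729, 1695 and 2167 for Bojungikgi-tang, Sayeok-tang and Banhasasim-tang at 20 ug/mL, and 2820, 502 and 223 for Yijung-tang at 500, 100 and 20 ug/mL. It gave 933 and 578 for 500 against 20 ug/mL with Bojungikgi-tang and Yijung-tang, 792 for Bojungikgi-tang against Sayeok-tang and 3453 for Banhasasim-tang against Yijung-tang. Vehicle replicate 3 had an SD of 0.091 around its group mean, and libraries with a larger SD were kept: Bojungikgi-tang 500 ug/mL replicate 2 (0.109) and 100 ug/mL replicate 2 (0.102).

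Leaving out 1 library gave 2453 to 3734 for Bojungikgi-tang at 500 ug/mL, 679 to 1942 at 100 and 325 to 698 at 20. For Sayeok-tang it gave 682 to 1133 at 100 ug/mL and 301 to 816 at 20, for Banhasasim-tang 1242 to 2450 at 100 and 86 to 898 at 20, and for Yijung-tang 12 to 35 at 100 and 5 to 10 at 20. Between 500 and 20 ug/mL the ranges were 668 to 3214 for Bojungikgi-tang and 2739 to 2895 for Banhasasim-tang. Between extracts at 500 ug/mL they were 672 to 2655 for Bojungikgi-tang against Sayeok-tang, and 2932 to 5028, 1286 to 2320 and 1321 to 1364 for Banhasasim-tang against Bojungikgi-tang, Sayeok-tang and Yijung-tang. The difference of dose effects had 50 to 275. The cause was not tested. Of 394 results for named genes, 7 lost their call with replicate number as a block. In 2067 checks of named genes without 1 library, 143 lost their call and 2 gained one. With only the libraries of the compared groups, 13 of 388 results lost their call and 8 gained one. The 208 list results came from the comparisons of 500 ug/mL with the vehicle and with 20 ug/mL. Of these, 31 lost their call with an estimated correlation and 5 with replicate number as a block. In 936 checks of these lists without 1 library, 30 lost their call and 15 gained one. No named gene, and none of these list results, was called in opposite directions under the alternatives above. Lists at the lower doses and between extracts were tried only with an estimated correlation.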

Other observations

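The tests for the genes shared at 20 ug/mL and the regroupings were fixed before their results. The tests on the size of the shared set after correction or without single libraries, on mitochondrial rRNA and on ER stress were chosen only after the result was seen.

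At 20 ug/mL 513 genes were called in all 3 replicated extracts, and 51 to 341 when any 1 of the 11 libraries was left out. Part of this excess over independent lists (0.23 higher and 1.04 lower) may come from the shared vehicle libraries. Those 3 cannot be divided into a pair of groups of at least 2. Simulated data with shared vehicle libraries and no true change never called 1 gene in all 3. They held no difference common to the vehicle libraries, so they cannot speak for or against one. Across genes the changes with Bojungikgi-tang and Sayeok-tang correlated at 0.674, against an average of 0.529 in the simulated data. After correction for GC content and length 511 genes were called in all 3 extracts, above the 67% set as arguing against a bias as the whole cause. Only 295 of the original 513 remained, so that total does not test what caused the original set. These were 57.5% of the calls, between the 33% and 67% set as limits, so a bias stays open. Shared genes that rose had a median GC content of 58% and length of 1386 bases. Those that fell had 44.4% and 865, and all tested genes 49.9% and 1053. For genes called in the other extracts at 20 ug/mL, the median further move by 500 ug/mL was 0.004 with Bojungikgi-tang, 0.036 with Banhasasim-tang and 0.076 with Sayeok-tang, against 0.239 to 0.261 from vehicle to 20 ug/mL. In the lone Yijung-tang library at 20 ug/mL, 99.8% of the 513 genes changed in the same direction, measured against the same vehicle libraries. The dose values leave both a fixed difference between vehicle and extract libraries and a response growing with dose open. The low-dose changes may therefore include a difference of handling or solvent. The same vehicle libraries served at every dose, so changes against the vehicle at 500 ug/mL may include it too.

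The rise of MT-RNR1 and MT-RNR2 with Banhasasim-tang was weighed against the explanations below. More RNA without a poly(A) tail stays open as a part of the rise. In 11 nuclear RNAs of that kind other than histones the median log2 change from 20 to 500 ug/mL was 0.425 (quartiles -0.413 and 0.642), with none called. The highest was 1.16 (RN7SL2), whereas the rRNA share went from 3.55 to 14.5% of counts. An even gain in all such RNA is therefore argued against as the whole cause. The set of 11 was chosen after a first test of 23 RNAs, 12 of them histones, which follow the cell cycle. That test had a median of -0.152 and had been read as arguing against more RNA without a tail. The limit was then also restated as an upper quartile below 0.5; as first written, a median below 0.5, it would have been met. A batch shared with the Yijung-tang libraries, whose codes start alike, was argued against by MT-RNR1 in the 3 Yijung-tang libraries. There it changed by 0.182, 0.395 and 0.512 at 500, 100 and 20 ug/mL, each with 1 library. One offset common to the Banhasasim-tang libraries alone was argued against as the whole cause by the dose steps in the rRNA share. That share was 3.55% (SD 0.098), 11.02% (SD 0.092) and 14.5% (SD 0.799) at 20, 100 and 500 ug/mL, with n = 2 each. An offset that added to the rise at every dose stays open. More mitochondrial RNA of every kind was argued against between 20 and 500 ug/mL by the 13 protein-coding transcripts. Their median log2 change between these doses was -0.519, with 7 called lower and 1 higher. At 100 ug/mL, however, their share of counts was 8.23%, against 6.9% at 20 ug/mL and 5.74% in the vehicle. The argument therefore does not cover 100 ug/mL. Slower decay or altered processing of mitochondrial transcripts could produce such a pattern, but no measurement here separates these.

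ER stress as the source of the ATF4 response to Banhasasim-tang was argued against at 100 ug/mL only. There the ER chaperone list had a median of -0.1, with 4 genes higher and 7 lower (-0.126 to -0.066 without any 1 of the 5 libraries). It was measured against the vehicle libraries, so a difference of handling or solvent common to all extract libraries could have shifted it, which limits the argument. At 500 ug/mL the median was 0.042, with 7 of its genes higher and 3 lower, with HYOU1 at 0.82 and XBP1 at 0.81, and the list rose between 20 and 500 ug/mL (camera adjusted p = 5.7e-05, adjusted p = 0.0276 with an estimated correlation). A contribution of ER stress at 500 ug/mL is therefore left open.

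Only comparisons among the vehicle, Bojungikgi-tang and Sayeok-tang were regrouped, so none with Banhasasim-tang or Yijung-tang has this check. Apart from the difference of dose effects, each regrouped comparison allowed only 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, called as many genes as the real count. The real count and the highest other were 3737 and 182 for Bojungikgi-tang at 500 ug/mL, 1694 and 0 at 100, and 1062 and 0 at 20. For Sayeok-tang they were 5229 and 1 at 500 ug/mL, 1632 and 1 at 100, and 1048 and 3 at 20. Between 500 and 20 ug/mL they were 1797 and 0 for Bojungikgi-tang and 2569 and 0 for Sayeok-tang, and between these extracts at 500 ug/mL 1419 and 83.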
